A study of Homo sapiens with 112 samples.

How the data were processed

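Gene expression was measured in formalin-fixed, paraffin-embedded bladder tumours, 28 sarcomatoid carcinomas (SARC) and 84 conventional urothelial carcinomas (UC), on Illumina HumanHT-12 DASL BeadChips. DASL (cDNA-mediated annealing, selection, extension and ligation) is an assay made for the fragmented RNA that fixed tissue yields. Each tumour was hybridised to a single array, and groups were taken from the sample titles.

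The values are the authors' deposited, normalized signals on a log scale, taken here as log2, 1 per probe and tumour. Per the submitters' processing notes, limma was used, with no version named. The background correction, the log base and any probe filter are not given in the sources used here. The sorted values of all 112 arrays differed by at most 0.00126, so the values had been brought to a single distribution across both tumour types before deposit. They ran from 4.01 to 9.33, and 26.6% lay within 0.01 of the lowest value. That floor sits just above log2 of 16, the offset that the neqc function of limma adds before taking log2, and base 2 was inferred from it and is not recorded. Were the values natural logs, the called genes would be the same and every fold would be larger. A gene at the floor in one group has a fold that understates its change. Detection p-values and scanner background were not used here, so the number of arrays and the distance from the floor limit the precision.

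The table held 29377 probes. The probe annotation gave 1 gene symbol for 27988 of them, several for 0, and 1389 are unnamed here. Entrez identifiers of 27819 probes were found in the RefSeq gene table, and 0 symbols had to be updated through them. XIST and Y-linked genes were left out before any test, which left 27885 probes of 19349 genes. A gene with several probes (5704 genes) was represented by the probe with the highest mean over all arrays. No table column lacked a sample, and the highest correlation between any 2 arrays was 0.957, so no pair looked like a tumour deposited again.

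The tumour types were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 19349 genes and a threshold of 0.05. A second count asked for a log2 fold change of at least 1 as well. Log2 fold changes are SARC minus UC and carry the standard error of the fit. Whole gene lists, 42 in all, fixed before the data were examined, were tested with camera of limma at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Each list also got a score per tumour, the mean of its members' log2 values after centring each gene on its mean over all arrays. Group means of scores were compared by a two-sided permutation test with 100000 resamples, whose smallest possible p is 1e-05, and by an exact permutation test over the means of the 19 slides (3876 regroupings). Spreads of scores, and 16 correlations within groups (8 pairs in each tumour type), were tested by permutation with Benjamini-Hochberg adjustment within each family. Scores and permutations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. The labels describe separate cases, and p-values measure the spread between these tumours.

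The genes named in the report follow a rule fixed at the same time as the lists. They are the 10 largest and 10 smallest log2 fold changes among called genes, a fixed set (CDH1, VIM, ZEB1, ZEB2, SNAI1, SNAI2, TWIST1, TGFB1, RHOA, KRT5, KRT14, KRT20, UPK2, GATA3, PPARG, FOXA1, FGFR3, ESRP1, CD274, CD8A, MKI67 and RB1), and from each list the 2 called members with the smallest p in the direction of most called members and 1 in the other direction. Genes with no named probe in the table were skipped. The result of 1 of the 42 lists is not reported here, though the list stays in the counts.

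The array descriptions have the form of a BeadChip barcode and a position, from which slide and chip lot were read. The 28 SARC arrays lay on 4 slides of 1 lot, and the UC arrays on 15 slides of 3 other lots with 8, 49 and 27 arrays (called lots 2, 3 and 4 here). No lot held both tumour types, so lot and tumour type cannot be told apart. The lots within UC were compared with each other to show how large differences between lots of a single tumour type were. Other alternatives were renormalization, another floor, the mean of all probes of a gene, a filter on dim genes, another variance model, array weights, the slide as a random block or as the replicate, array position, single UC lots, leaving out each SARC slide, and the number in the title as a block.

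The gene test was tested on simulated data with the real group sizes, means and variances over 19349 genes. For the comparison of 28 SARC with 84 UC, it recovered 84% of 100 genes shifted by 0.5 on the log2 scale and 99% of 100 genes shifted by 1, and 4.46% of its calls fell on unshifted genes. The shifted genes were drawn from those above a minimum spread. The simulated noise was normal and independent between genes, with no floor and no slide or lot effect. The recovery and error rates hold for those conditions and were not tested for the real arrays.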

Results

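Transcript levels were compared between 28 sarcomatoid carcinomas of the bladder (SARC), tumours in which malignant urothelium takes on a spindle-cell, sarcoma-like form, and 84 conventional urothelial carcinomas (UC). The series title places the comparison in the question of how epithelial-to-mesenchymal transition (EMT) relates to progression to the sarcomatoid form. After the authors' normalization each array had the same distribution of values, with a median of 4.26 and quartiles of 4.01 and 5.24 on the log2 scale. Arrays of the same tumour type had a median correlation of 0.869 within SARC and 0.883 within UC, against 0.841 between the types, over all probes. All SARC arrays came from a chip lot that held no UC array.

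The largest decreases in SARC were in transcripts of differentiated urothelium and of epithelial cells. The 10 lowest genes included the uroplakins UPK1A (5.19-fold lower) and UPK2 (4.86-fold lower), membrane proteins of the urothelial surface, together with ELF3, an epithelial transcription factor (4.42-fold lower), and RAB25, a GTPase of epithelial membrane recycling (4.44-fold lower). UPK2 averaged 4.07 ± 0.12 (SD, n = 28) in SARC, where 71.4% of arrays were at the floor, against 6.35 ± 1.57 (SD, n = 84) in UC. The other genes among the 10 lowest were MYH14, a nonmuscle myosin heavy chain (log2 fold change -2.41 ± 0.20, SE), the calcium-binding protein S100P (-2.30 ± 0.24), the mucosal chemokine CXCL17 (-2.20 ± 0.21), LAD1 (-2.15 ± 0.19), FXYD3, a regulator of the sodium pump (-2.09 ± 0.14), and the surface antigen PSCA (-2.03 ± 0.27). Their adjusted p ranged from 5.29e-24 for FXYD3 to 2.36e-09 for UPK1A. CXCL17 was at the floor on 60.7% of SARC arrays.

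Among genes at least 2-fold different fewer rose in SARC than fell. The 10 highest were led by RFLNB, an actin-organising partner of filamin (3.12-fold higher, adjusted p = 4.44e-13), the immunoglobulin superfamily member IGSF21 (log2 fold change 1.58 ± 0.14, SE, 1.36e-17), UHRF1, which binds hemimethylated DNA (2.93-fold higher, 6.63e-12), and PSRC1, a spindle protein (2.89-fold higher, 1.67e-18). They were followed by the tRNA-modifying enzyme DUS3L (log2 fold change 1.48 ± 0.16, SE), the transcobalamin receptor CD320 (1.45 ± 0.17), RENBP (1.43 ± 0.15), CYP26B1, which degrades retinoic acid (1.40 ± 0.19), the glycosyltransferase GALNT10 (1.38 ± 0.15) and the elongator subunit ELP4 (1.34 ± 0.13). A second UHRF1 probe did not differ (0.15, adjusted p = 0.366), and RFLNB lost its call against the 8 UC tumours of lot 2.

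Across all 19349 genes, limma called 7347, of which 3866 were higher and 3481 lower in SARC. At least a 2-fold difference was seen for 248 genes, 56 higher and 192 lower. The 56 were 28 with the mean of all probes of a gene, 100 against lot 3 alone and 104 without SARC slide 2. The median log2 fold change over all genes was 0.0026. With the 19 slide means as replicates, 3268 genes were called, and against lot 4 alone, 4348. Against lot 2 alone, 3046 genes were called, 430 of them at least 2-fold.

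**Figure D1:**
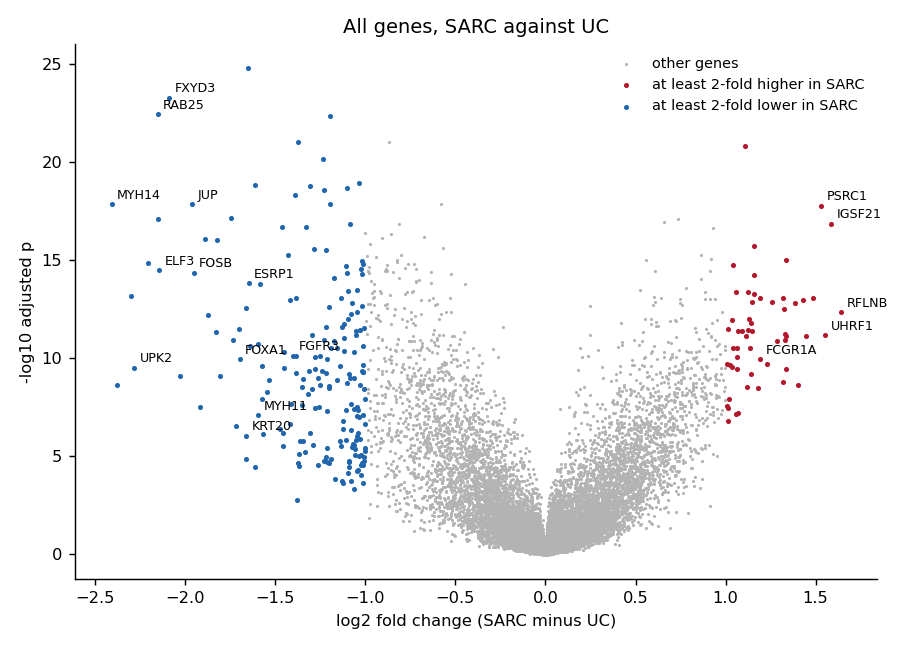
Each point is a gene, with the log2 fold change (SARC minus UC) on the horizontal axis and -log10 of the adjusted p from limma on the vertical axis; coloured points are called and at least 2-fold different. The 192 coloured genes on the left outnumber the 56 on the right, and UPK2, RAB25, ELF3 and FXYD3 are among those farthest left.

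Of the 42 gene lists, camera called 12 at the preset correlation, 11 lower in SARC and 1 higher. With an estimated correlation 3 of them held (luminal urothelial markers, tight junction and epithelial regulators), while fry called 22, 3 higher and 19 lower. Beyond those of camera, the lists fry called included macrophage and NK cell genes (higher) and mesenchymal markers, collagens, B cell genes, p53 targets, PPAR, oxidative phosphorylation and reference genes (lower). The squamous, adherens junction, dendritic and mast cell, ribosomal, immediate early and cell cycle lists each lost their camera call when some of the tumours or genes were left out. Random regroupings of the same tumours called up to 19 lists at the preset correlation. Member counts below use the adjustment over all genes, and the counts adjusted over the list alone were the same unless both are given.

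Luminal urothelial markers were lower: 24 of 27 measured members fell in SARC and none rose (camera adjusted p = 2.84e-14, and adjusted p = 0.0386 with an estimated correlation). KRT20, a keratin of the surface cells, was 3.16-fold lower (5.83 ± 1.49 in UC, SD, n = 84, against 4.17 ± 0.50 in SARC, n = 28). The luminal transcription factors FOXA1 (3.24-fold lower, adjusted p = 1.09e-10), GATA3 (log2 fold change -0.58 ± 0.16, SE, 0.00239) and PPARG (1.43-fold lower, 0.00603) fell by different amounts, and PPARG lost its call over slide means (adjusted p = 0.172). ADIRF, abundant in both types, was 2.02-fold lower. GATA3 was no longer called against lot 2 alone.

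Basal markers did not pass camera or fry. Of 15 basal urothelial markers, 3 fell and none rose (camera adjusted p = 0.108), with TRIM29 (2.73-fold lower) and the hemidesmosome integrin ITGB4 (1.91-fold lower) having the smallest p, and of its other probes, 1 was lower too (-1.35, adjusted p = 3.69e-12) and another did not differ (0.089, 0.665). KRT5, the keratin of basal cells, had a log2 fold change of -0.73 ± 0.32 (SE, adjusted p = 0.0619) and KRT14 of -0.086 ± 0.39 (adjusted p = 0.893). Both varied widely within SARC, with SDs of 1.59 for KRT5 and 1.74 for KRT14 (n = 28). Among squamous differentiation genes 5 of 19 fell and none rose (adjusted p = 0.03, and adjusted p = 0.761 with an estimated correlation), led by the cornified envelope proteins SPRR1A (3.29-fold lower) and SPRR3 (2.35-fold lower).

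**Figure D2:**
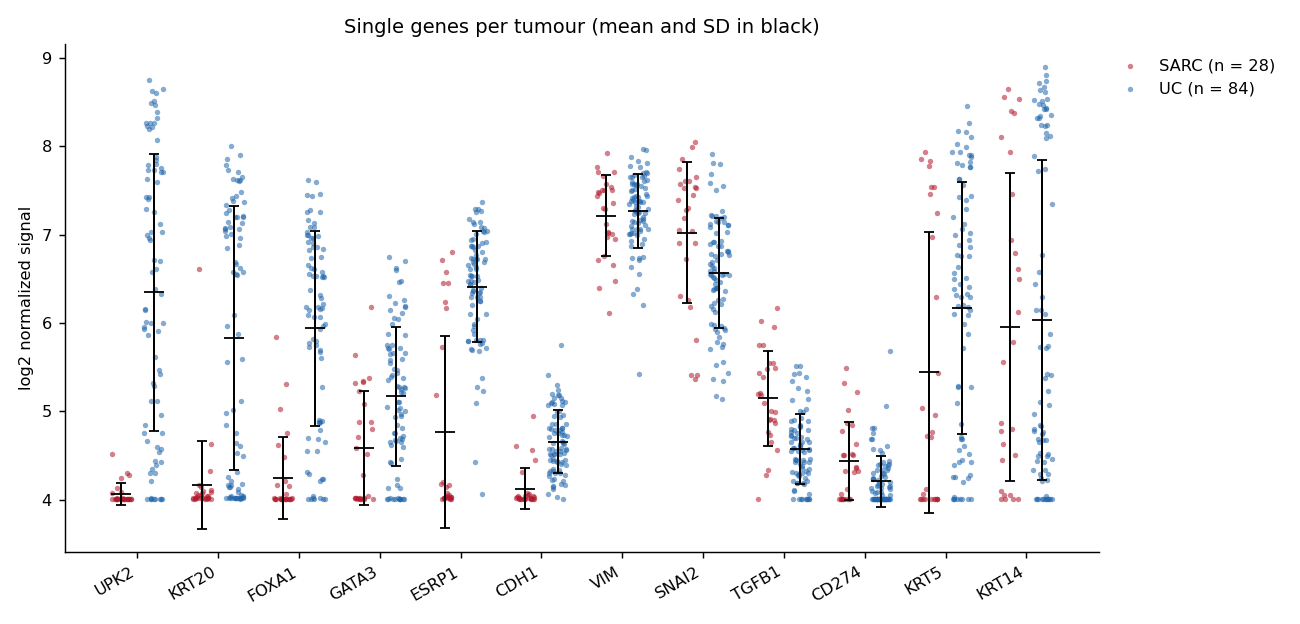
Log2 normalized signal of 12 genes in each tumour (red, SARC; blue, UC), with the group mean and SD in black; values at the bottom lie at the floor of 4.01. UPK2, KRT20, FOXA1, ESRP1 and CDH1 sit lower in SARC, VIM overlaps between the types, and KRT5 and KRT14 spread over several log2 units in both.

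Regulators of the epithelial state were lower, by different amounts among SARC tumours. Of 18 epithelial regulators 16 fell and none rose (adjusted p = 1.86e-16, and adjusted p = 0.0152 with an estimated correlation), or 17 lower and 1 higher when adjusted over the list alone. ESRP1, which directs epithelial splicing, was 3.13-fold lower (adjusted p = 1.45e-14) and the membrane protease ST14 2.62-fold lower (4.78e-19). The 5 SARC tumours highest in the basal score, a subset chosen after the values were seen, averaged 6.54 ± 0.25 (SD) for ESRP1 against 4.38 ± 0.75 in the other 23 and 6.41 ± 0.63 in UC. Their CDH1 averaged 4.58 ± 0.24, against 4.02 ± 0.020 in the other 23. Tight junction genes fell in 12 of 17 cases, 14 when adjusted over the list alone, and none rose (adjusted p = 9.32e-08, and adjusted p = 0.0266 with an estimated correlation). TJP1 (ZO-1) was 1.85-fold lower and the polarity protein PATJ 1.96-fold lower.

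Desmosome and adherens junction genes passed camera only at the preset correlation, and fry called both lower (adjusted p = 3.89e-07 and 2.38e-06). Of 11 desmosome genes 7 fell and none rose (adjusted p = 0.000493, and adjusted p = 0.355 with an estimated correlation), with envoplakin (EVPL) 3.54-fold and plakophilin 2 (PKP2) 2.13-fold lower. Of 12 adherens junction genes 6 fell and 3 rose (adjusted p = 0.0214, and adjusted p = 0.355 with an estimated correlation). Plakoglobin (JUP) was 3.90-fold lower, though its other probes fell by less (log2 fold changes of -0.66 and -0.52), and EPCAM was 2.61-fold lower. The nectin-like receptor PVR was 1.64-fold higher, with other PVR probes at 0.26 (adjusted p = 0.00411) and -0.0077 (0.955). CDH1, the E-cadherin gene, was 1.45-fold lower (4.12 ± 0.23 against 4.66 ± 0.36, SD, n = 28 and 84, adjusted p = 1.21e-09), and 50% of SARC arrays were at the floor.

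The EMT transcription factors did not pass camera or fry. Of 10 measured, 2 rose and none fell (adjusted p = 0.579): SNAI2 (1.37-fold higher, adjusted p = 0.00816) and FOXC2 (1.55-fold higher, 0.000207). A second SNAI2 probe was higher too (log2 fold change 0.56, adjusted p = 2.27e-05). The SNAI2 probe used lost its call over slide means (adjusted p = 0.184). ZEB1 (log2 fold change 0.0053 ± 0.039, SE, adjusted p = 0.935), ZEB2 (0.042 ± 0.034, 0.346) and TWIST1 (0.15 ± 0.11, 0.272) did not pass the test. SNAI1 was at the floor on 100% of SARC and 97.6% of UC arrays, so a decrease could not have been seen. No SARC array rose above the floor, by a probe whose sensitivity was not tested. VIM, the intermediate filament of mesenchymal cells, was high in both types (7.21 ± 0.46 in SARC and 7.26 ± 0.42 in UC, SD, adjusted p = 0.713). A second VIM probe was not called either, with a log2 fold change of 0.195 (adjusted p = 0.0715).

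Neither mesenchymal markers nor collagens passed camera, though fry called both lower (adjusted p = 0.0392 and 0.0324), and called collagens went both ways. Among 16 mesenchymal markers 6 fell and none rose, or 7 lower and 1 higher when adjusted over the list alone (adjusted p = 0.108), led by the proteoglycans LUM (1.88-fold lower) and DCN (1.55-fold lower). Of 14 collagens 6 fell and 2 rose (adjusted p = 0.0836), with COL3A1 1.96-fold and COL6A3 1.78-fold lower and COL6A1 1.35-fold higher. Matrix proteases and inhibitors had 2 higher and 2 lower of 15 (adjusted p = 0.776): the gelatinase MMP9 was 1.53-fold higher, MMP14 1.06-fold higher near the floor, and the inhibitor TIMP3 1.87-fold lower. Integrins had 4 higher and 4 lower of 14 (adjusted p = 0.545), with ITGB6, an epithelial integrin, 3.12-fold lower, and ITGB3 and ITGA4 1.14-fold and 1.05-fold higher at levels near the floor.

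In the TGF-beta pathway 6 of 15 genes rose and 3 fell (adjusted p = 0.776). TGFB1 was 1.49-fold higher (5.15 ± 0.54 against 4.57 ± 0.40, SD, adjusted p = 2.77e-07) and its induced matrix protein TGFBI 1.45-fold higher, while the SMAD corepressor SKIL was 1.32-fold lower. RHOA fell slightly (log2 fold change -0.30 ± 0.072, SE, adjusted p = 0.000398) and lost its call over slide means (adjusted p = 0.113).

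Smooth muscle transcripts were lower in SARC. Of 10 smooth muscle and myofibroblast genes 9 fell and none rose, with 1 higher when adjusted over the list alone (adjusted p = 5.07e-05, and adjusted p = 0.355 with an estimated correlation). The myosin heavy chain MYH11 was 3.02-fold and the actin ACTG2 1.64-fold lower. Skeletal muscle genes had no call among 10 (adjusted p = 0.92). Cartilage and bone genes had 4 higher and 2 lower of 13, or 5 and 2 when adjusted over the list alone (adjusted p = 0.579), with ALPL 1.56-fold and ACAN 1.40-fold higher and the cartilage matrix protein COMP 2.13-fold lower.

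No other tissue list passed camera. Of 11 endothelial genes 2 fell, TIE1 (1.36-fold) and KDR (log2 fold change -0.14), and none rose (adjusted p = 0.59). Neuroendocrine and neural genes had 2 higher and 1 lower of 9 (adjusted p = 0.818), with TUBB3 1.65-fold and ENO2 1.14-fold higher and SOX10 1.07-fold lower near the floor. Adipocyte genes had 1 higher (LEP, 1.30-fold) and 1 lower (CIDEA, 1.42-fold) of 7 (adjusted p = 0.818), erythrocyte genes 2 lower of 7 (HBA2, 1.27-fold, and HBB, 1.39-fold; adjusted p = 0.545), and prostate genes 1 lower of 6 (TMPRSS2, 1.66-fold; adjusted p = 0.299).

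Of the immune lists only dendritic and mast cell genes passed camera, and only at the preset correlation. Macrophage and monocyte genes had 6 higher and 1 lower of 15, or 7 and 1 when adjusted over the list alone (adjusted p = 0.0733). FCGR1A, a high-affinity IgG receptor, was 2.29-fold higher (adjusted p = 1.1e-10) and the scavenger receptor MSR1 1.41-fold higher, while CD68 was 1.21-fold lower. Dendritic and mast cell genes had 5 lower of 10 and none higher (adjusted p = 0.0158, and adjusted p = 0.355 with an estimated correlation), led by the mast cell proteases TPSAB1 (2.33-fold lower) and CPA3 (1.64-fold lower). B and plasma cell genes had 2 lower of 9 (CD79A, 2.03-fold, and POU2AF1, 1.72-fold; adjusted p = 0.116), and neutrophil genes 2 lower (ELANE, 1.34-fold, and S100A12, 1.11-fold) and 1 higher (FCGR3B, 1.03-fold) of 9 (adjusted p = 0.818).

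T cell genes had 1 call among 13, CD6 (1.34-fold higher, list adjusted p = 0.776). The CD8A probe used had a log2 fold change of -0.023 ± 0.095 (SE, adjusted p = 0.881), whereas its 2 other, dimmer probes were higher (0.49, adjusted p = 5.74e-06, and 0.18, 0.0339). Cytotoxic and NK cell genes had 5 higher of 11 and none lower (adjusted p = 0.196), including GZMH (1.35-fold) and KLRK1 (1.04-fold, near the floor). Immune checkpoint genes had 3 higher and 1 lower of 11 (adjusted p = 0.547): PDCD1LG2, encoding PD-L2, was 1.62-fold and LAG3 1.41-fold higher, and VTCN1 1.53-fold lower. CD274, encoding PD-L1, was 1.17-fold higher (adjusted p = 0.00878) at levels close to the floor, and lost its call over slide means (adjusted p = 0.324).

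MHC class I presentation genes had 5 higher and 1 lower of 11 (adjusted p = 0.545), with the immunoproteasome subunit PSMB8 1.36-fold and the peptide transporter TAP1 1.67-fold higher and TAPBP 1.25-fold lower. MHC class II genes had 2 lower of 8 (HLA-DMA, 1.44-fold, and HLA-DPB1, 1.08-fold; adjusted p = 0.545). Interferon response genes had 3 higher and 1 lower of 16 (adjusted p = 0.948), with ISG15 1.58-fold and IRF7 1.36-fold higher and GBP2 2.39-fold lower.

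Proliferation genes were the only list called higher, and against lot 3 alone, with 49 UC tumours, they lost the call. Of 22 cell cycle genes 10 rose and none fell (adjusted p = 0.00901, and adjusted p = 0.704 with an estimated correlation), including RRM2, a subunit of ribonucleotide reductase (1.84-fold), and the mitotic kinase AURKA (1.56-fold). MKI67 did not pass the test (log2 fold change 0.10 ± 0.19, SE, adjusted p = 0.71). RB and cell cycle control genes had 3 higher and 5 lower of 15 (adjusted p = 0.776): the D cyclins CCND2 (1.71-fold) and CCND1 (1.66-fold) were lower and E2F1 1.30-fold higher, and RB1 was at 0.25 ± 0.12 (SE, adjusted p = 0.075). Among 11 p53 targets 2 rose and 4 fell (adjusted p = 0.0964), with GDF15 2.55-fold and FAS 1.49-fold lower and MDM2 1.51-fold higher, a call that 2 other MDM2 probes did not share.

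Receptor tyrosine kinases fell in 10 of 16 cases and rose in 2 (adjusted p = 0.00531, and adjusted p = 0.0601 with an estimated correlation). Of its members, FGFR3, ERBB2 and ERBB3 are also in the luminal list, so the results of these lists are not independent. FGFR3, a receptor often altered in bladder tumours, was 2.64-fold lower (6.84 ± 1.03 against 8.24 ± 0.72, SD, adjusted p = 7.42e-11) and ERBB3 3.02-fold lower, while AXL rose slightly near the floor (log2 fold change 0.14 ± 0.037, SE). Other, dimmer probes fell by less: FGFR3 by -0.45 and ERBB3 by -0.61 and -0.46 (log2 fold changes).

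None of the metabolic lists passed camera. PPAR and lipid metabolism genes had 2 higher and 5 lower of 10 (adjusted p = 0.244), with ACSL5 (log2 fold change -1.05) and FASN (-0.27) lower and RXRA 1.47-fold higher. Glycolysis and hypoxia genes had 3 higher and 1 lower of 15 (adjusted p = 0.948), with ENO1 1.23-fold and PKM 1.14-fold higher and SLC2A1 1.27-fold lower, and 2 other PKM probes did not rise. Oxidative phosphorylation genes had 1 higher and 7 lower of 13, or 2 and 7 when adjusted over the list alone (adjusted p = 0.0774), with CS 1.39-fold and NDUFS1 1.16-fold lower and UQCRC1 1.28-fold higher. Of 3 other CS probes, 2 were lower as well (-0.45 and -0.41) and 1 went the other way (0.48, adjusted p = 0.000519).

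Ribosomal protein genes had 1 higher and 7 lower of 14 (adjusted p = 0.00358, and adjusted p = 0.355 with an estimated correlation), with RPL5 1.62-fold and RPS4X 1.63-fold lower and RPL13 1.39-fold higher, where a second RPL13 probe was lower (-0.17, adjusted p = 0.00802). Immediate early and heat shock genes, which respond to handling of tissue among other stimuli, had 1 higher and 8 lower of 13 (adjusted p = 0.0103, and adjusted p = 0.355 with an estimated correlation). FOSB was 3.87-fold and JUNB 1.40-fold lower, and IER2 1.04-fold higher near the floor. Reference genes had 2 higher and 3 lower of 10 (adjusted p = 0.545), with YWHAZ and HPRT1 each 1.25-fold lower and TBP 1.51-fold higher, and a second HPRT1 probe was higher (0.23, adjusted p = 0.00366). Among further probes of the named genes that lay well above the floor, 30 were called with the same sign as the probe used, 3 with the opposite sign and 13 were not called although the probe used was. Among the genes with such an uncalled probe were CD68, CD79A, IRF7 and PSMB8. The median, mean and camera direction differed in sign for the skeletal muscle, cartilage and bone, interferon response, RB and cell cycle control, and neuroendocrine lists.

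Scores per tumour showed how far the groups parted and where they overlapped. Every one of the 28 SARC tumours lay below the UC median for luminal markers (mean -0.75 against 0.25 in UC), epithelial regulators (difference of means -0.92) and receptor tyrosine kinases (-0.39), and 27 of 28 for tight junctions (-0.51), each with a permutation adjusted p of 4.2e-05, from the smallest p the resamples can give. Below the lowest UC tumour lay 17 SARC tumours for luminal markers, 9 for epithelial regulators and 6 each for tight junctions and receptor tyrosine kinases. The other SARC tumours lay within the UC range. For epithelial regulators the highest SARC tumour, at 0.268, lay above the UC mean of 0.229. In all, 23 of 42 list scores differed, 4 higher and 19 lower, and 15 did so over slide means, 2 higher and 13 lower.

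The 4 higher scores were cell cycle (0.27, higher than the UC median in 25 of 28 tumours, adjusted p = 0.00042), macrophage (0.25, 22 of 28, 0.00989), EMT factors (0.11, 19 of 28, 0.0226) and neuroendocrine genes (0.094, 20 of 28, 0.0254). Of these only cell cycle was called over slide means, where MHC class I presentation was also called higher (0.21, exact permutation adjusted p = 0.0383). Smooth muscle (-0.80, lower than the UC median in 24 of 28) and immediate early genes (-0.40, 26 of 28) were lower in both tests. The mesenchymal score was lower by permutation over tumours (-0.20, 19 of 28, adjusted p = 0.0204) but not over slide means (exact permutation adjusted p = 0.105).

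**Figure D3:**
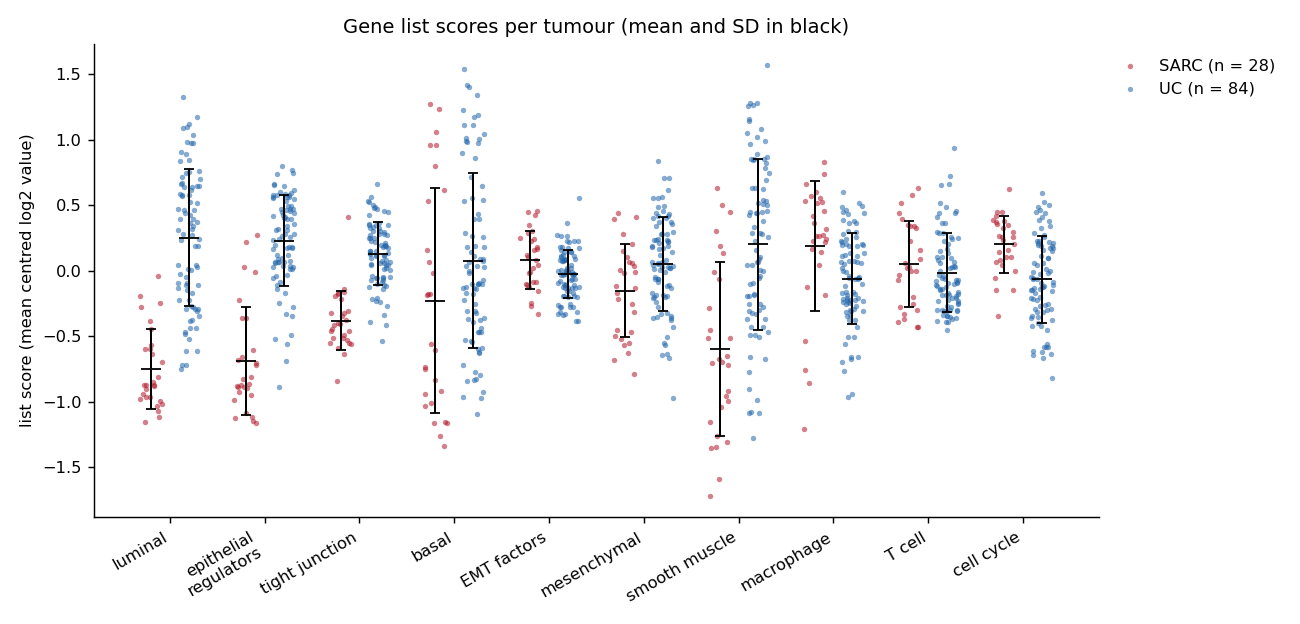
Score of 10 gene lists in each tumour (red, SARC; blue, UC), in log2 units around the mean of all arrays, with the group mean and SD in black. All 28 SARC tumours lie below the UC median of the luminal and epithelial regulator scores, some of them within the UC range. The types overlap more widely for the EMT factor, mesenchymal and T cell scores.

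The luminal score had an SD of 0.305 in SARC and 0.524 in UC (ratio 0.583, permutation adjusted p = 0.0181 over 42 lists), and no other list passed the test of spread. UPK2 and FOXA1 were at the floor on 71.4% and 60.7% of SARC arrays, where a value cannot fall further, so this ratio is not evidence that SARC tumours vary less. With scores centred within slides the ratio was 0.617 (adjusted p = 0.055).

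Of the 16 correlations within types (8 pairs in each type), 6 passed in all. The luminal and basal scores rose together in SARC (r = 0.60, permutation adjusted p = 0.0032; rank correlation 0.59, 0.00524; n = 28) and opposed each other in UC (r = -0.37, 0.0032; rank correlation -0.29, 0.0248; n = 84). Without the 2 tumours farthest from the median of the luminal score, r was 0.68 in SARC and -0.38 in UC, and within slides it was 0.59 and -0.42. Neither correlation passed without the tumours highest in the basal score, a check chosen after the values were seen. There r was 0.18 over the other 23 SARC tumours (permutation p = 0.409) and 0.015 over 69 UC tumours, with 15 left out (p = 0.905). Such a cut narrows the range of the basal score, which by itself weakens a correlation. It therefore does not show that those tumours alone carry either correlation. CD274, tested against the T cell score, averaged 4.27 over all arrays, close to the floor, which limits its correlations. The T cell score rose with CD274 in SARC (r = 0.62, adjusted p = 0.0032; rank correlation 0.63, 0.00331) and in UC (r = 0.29, adjusted p = 0.0236; rank correlation 0.37, 0.00331), with r of 0.61 and 0.35 without the 2 extreme tumours and 0.61 and 0.29 within slides.

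In UC the mesenchymal score opposed the epithelial regulator score (r = -0.37, permutation adjusted p = 0.0032; rank correlation -0.47, 0.00016) and the luminal score (r = -0.31, 0.0118; rank correlation -0.27, 0.034), with r of -0.36 and -0.27 without the 2 extreme tumours and -0.34 and -0.31 within slides. Without those 2 tumours the rank correlation with the luminal score no longer passed (rank correlation -0.24, adjusted p = 0.0817). The same pairs had r of -0.32 (adjusted p = 0.163) and -0.19 (0.424) in SARC. The EMT factor score with CDH1 gave r = -0.19 in SARC (0.424) and -0.20 in UC (0.15). In UC this pair passed only on values centred within slides (r = -0.33, 0.0072). CDH1 averaged 4.02 ± 0.020 (SD), close to the floor, in the 23 SARC tumours outside the 5 highest in the basal score. So little variation of CDH1 means that the r in SARC does not show the absence of a relation.

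**Figure D4:**
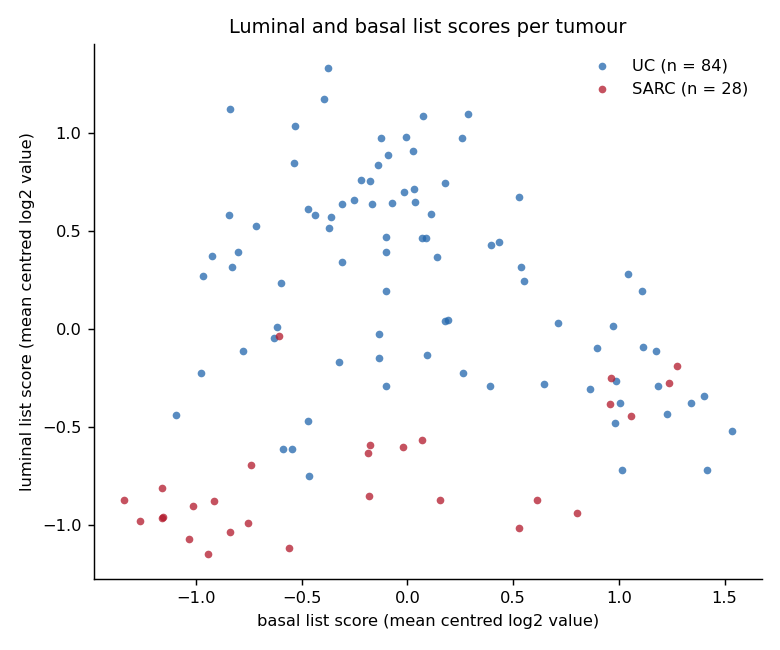
Basal list score (horizontal axis) against luminal list score (vertical axis) for each tumour, in log2 units around the mean of all arrays; blue, UC; red, SARC. The scores correlate at r = 0.60 in SARC and r = -0.37 in UC. Without the 5 SARC tumours farthest right, r is 0.18 in SARC, over a narrower range of basal scores.

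Conventional tumours differed between chip lots as well. Over the 3 lots of 84 UC tumours, the F test of limma called 2787 genes. Lot 2, with 8 tumours, differed from lot 3 in 2646 genes (210 at least 2-fold) and from lot 4 in 1846 (111 at least 2-fold), while lots 4 and 3 differed in 265 genes (0 at least 2-fold, 2961 genes at an unadjusted p under 0.05). With the slide as a random block these counts were 2006, 1169 and 75. Mean luminal scores were 0.15, 0.25 and 0.27 in lots 2, 3 and 4 against -0.75 in SARC, so for this score lots of UC differed by far less than the types did. That was not so for proliferation, with mean cell cycle scores of -0.31, -0.036 and -0.049 against 0.20 in SARC, where lot 2 lay as far from lot 3 as SARC did from UC (0.27). What separates lots of UC, whether chips, handling or the tumours themselves, is not recorded in the labels.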

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

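The tests of the difference described here were chosen after the correlations had been seen. The correlation of the luminal with the basal score differed between the tumour types, with r in SARC minus r in UC of 0.968 (r = 0.60 over 28 SARC and -0.37 over 84 UC tumours; permutation of tumours between the types after centring and scaling within each, p = 5e-05, adjusted p = 0.0004 over 8 pairs). Without the 5 SARC tumours highest in the basal score the difference was 0.56 (permutation p = 0.0115, not adjusted over the pairs). With the 15 such UC tumours left out as well it was 0.17 (permutation p = 0.476). Leaving out tumours by the basal score narrows the range of that score, which by itself weakens a correlation. These values therefore do not show that the difference rests on those tumours. No other pair differed, and the T cell score with CD274 came nearest (difference 0.336, adjusted p = 0.293). Luminal genes such as UPK2 and FOXA1 were at the floor on 71.4% and 60.7% of SARC arrays. CD274 averaged 4.27 over all arrays, close to the floor, which limits the comparison of its correlations.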

How the results depend on the processing

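Reading the values as natural logs, leaving out lot 2 and leaving out the tumours highest in the basal score were alternatives chosen after seeing the data, and the cause of each change below was not tested unless it is stated. All 7347 called genes, 248 genes at least 2-fold and 12 lists are the main counts. Over slide means, 3268 genes were called, 3234 of them shared with the main count, from far fewer replicates. UC lot 2 alone, with 8 tumours, gave 3046 genes (2248 shared) and 430 at least 2-fold (134 shared), and lot 4 alone 4348 genes (4180 shared). Read as natural logs, 929 genes were at least 2-fold different by construction. An estimated correlation left 3 lists and fry called 22. Slide means left 15 list scores. For spread, 0 lists passed with scores centred within slides and 4 against lot 3 alone.

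Without lot 2, 7377 genes, 268 at least 2-fold and 12 lists were called. Leaving out each SARC slide gave 6045 to 7157 genes, 246 to 309 at least 2-fold and 12 to 14 lists. Without SARC slide 2 the squamous and ribosomal lists lost their call and 3 other lists gained one. The 56 genes at least 2-fold higher were 59 to 104 in these fits, 28 with the mean of all probes, 148 against lot 2 alone and 100 against lot 3 alone. The cell cycle list, the only one higher, lost its call against lot 3 alone, where 9 lists were called. Centring arrays on their medians gave 8788 genes with 62.5% higher, against 52.6%. Counts under the other alternatives stayed within 1.5 times of them. Of 138 named genes 50 kept direction and side of the threshold under every alternative, as did 29 of 42 lists. Most losses came with lot 2 alone (63 genes) and slide means (37 genes).

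The sign turned for 9 of 128 called and 9 uncalled named genes. Median centring turned SNAI1 (0.0098), and array weights ZEB1 (-0.035) and CD8A (0.066). The mean of all probes turned VIM (0.072), CD8A (0.22, limma adjusted p = 0.0103, so called higher) and PKM (-0.0037). Slide means turned KRT14 (0.23) and CD8A (0.043). Lot 2 alone turned TWIST1 (-0.15), RHOA (0.10), CD8A (0.094), RAC1 (0.16), TIE1 (0.086), KDR (0.059), TAP1 (-0.030), TAPBP (0.10), RXRA (-0.12) and YWHAZ (0.052). Lot 3 alone turned ZEB1 (-0.0089) and MKI67 (-0.13), lot 4 alone CD8A (0.087), and leaving out lot 2 ZEB1 (-0.0025) and MKI67 (-0.045). Leaving out each SARC slide in turn, ZEB1 ranged from -0.043 to 0.029, ZEB2 from -0.0094 to 0.073, KRT14 from -0.20 to 0.23, CD8A from -0.099 to 0.11 and MKI67 from -0.053 to 0.30.

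Numbers in the titles run in both types but do not pair tumours: 3 of 28 same-numbered pairs correlated above 0.1 (median -0.029), and 2 SARC arrays correlated best with their own number. With the number as a replicate block, UC tumours whose number no SARC tumour carries drop out of the difference. That fit therefore compared the 28 SARC tumours with the 28 same-numbered UC tumours. It called 5202 genes, 291 at least 2-fold (88 higher) and 9 lists (4 lost their call, receptor tyrosine kinases among them). VIM (0.13), KRT5 (0.21) and KRT14 (1.25, adjusted p = 0.0156, so called higher) turned sign. Many of the UC tumours that dropped out were high in KRT14, so its value is against a different set of UC tumours. An offset before log2 was not run, since the values were already logs. Without the tumours highest in the basal score, the correlation of luminal with basal scores was 0.18 in SARC, no longer past the test, and turned sign in UC (0.015). Distance from the floor limits small changes of dim genes.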

Other observations

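Several gene families were singled out because their members had been seen to differ, so their counts describe the data and no test of them is given. Fc gamma, LILR and SIGLEC receptors, which myeloid cells express and of which a few are also in the fixed lists, had 17 higher and 1 lower of 33 measured (11 near the floor). LILRA3 was at 0.95 and SIGLEC9 at 0.64 (log2 fold changes). Protocadherins, cell adhesion molecules of the nervous system, had 33 higher and 2 lower of 68, but 39 lay near the floor, where called genes were mostly higher in general. Centromere proteins had 10 higher and 1 lower of 22 (4 near the floor), with CENPS at 0.87 and CENPT at 0.60, and kinesins 16 higher and 4 lower of 39 (14 near the floor), with KIF18B at 0.89 and KIF5B at -0.46. Cancer-testis antigens had 11 higher and none lower of 50 (38 near the floor), and olfactory receptors, taken for comparison, 16 higher and 1 lower of 383 (371 near the floor).

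Near the floor, called genes were mostly higher in SARC. Of the 7680 dimmest genes, 992 were called higher and 340 lower, with a median absolute change of 0.0888, against 1764 higher and 2080 lower among 6827 genes with a mean above 5. The cell cycle inhibitor CDKN2A, also singled out after its value was seen, was 1.89-fold higher in SARC (6.24 ± 1.38 against 5.32 ± 1.16, SD, n = 28 and 84, adjusted p = 0.00328).

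All tests in the paragraphs that follow were chosen after the result was seen, except the comparison of small nucleolar RNAs between lots. Whether tumours assigned to groups at random give as many calls was tested with 100 splits of the same sizes, the real split included. For the 7347 called genes 1 split of 100 gave as many (highest other 83), for the 248 genes at least 2-fold 1 split (highest other 0), and for the 2787 genes between UC lots 1 split (highest other 740), so no random assignment came near these counts. For the 12 gene lists 20 of 100 splits called as many (highest other 19), so chance cannot be excluded for that count at the preset correlation. When whole UC slides were drawn instead, 4 against 11 in 100 draws, up to 1966 genes were called (median 1) and up to 18 at least 2-fold. The highest counts point to a structure of slides or lots within UC. Each UC slide lies in a single lot, so these draws cannot tell slides from lots.

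The first pattern is the 192 genes at least 2-fold lower in SARC. A signal of a single probe explains them poorly: 39 other probes of 32 of these genes had a median log2 fold change of -0.971, against -0.155 to 0.154 for random lists of such probes. Whether a lower share of epithelial cells explains them was not settled. The smooth muscle score changed by -1.05 relative to the macrophage score (95% bootstrap interval -1.38 to -0.702), so other cell types did not change alike. Muscle and immune cells can differ between tumours on their own, so this value does not decide whether the epithelial share was lower. Between UC lots, 166 genes at least 2-fold lower against lot 4 alone (median -1.23) had a median of -0.118 in lot 2 minus lot 3, with 103 negative, below the -0.058 to 0.091 that held 95% of 10000 expression-matched lists. That contrast leaves out the SARC lot, so it decides nothing about chip lot, which cannot be told apart from the tumour type, and the biological explanation stays untested.

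The second pattern is the 56 genes at least 2-fold higher in SARC, which were 28 with the mean of all probes and 104 without SARC slide 2. Between UC lots, 51 genes at least 2-fold higher against lot 4 alone (median 1.14) had a median of 0.329 in lot 2 minus lot 3, with 43 positive, above the -0.123 to 0.156 of matched lists. A signal of a single probe as the whole cause is argued against by 10 other probes of 9 genes, whose median was 0.368 (-0.311 to 0.309 for random lists), well under the 1.14 of the probes used. These genes vary between UC lots, but the contrast leaves out the SARC lot, so whether chip lot or tumour type raised them stays open.

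The third pattern is a lower level of small nucleolar RNAs, guides for chemical modification of ribosomal RNA: 173 of 266 were lower and 7 higher in SARC, with a median log2 fold change of -0.27, and SNORA1 fell by 1.65. Their median was lower on all 4 SARC slides (-0.39, -0.27, -0.27 and -0.20). A lower yield of short RNAs is consistent with 48 other short noncoding RNAs, whose median was -0.176, below the -0.089 to 0.055 of matched lists. Between lots of UC the largest median difference of small nucleolar RNAs was 0.00882, so those lots gave no sign of it, but the SARC lot holds no UC tumour and cannot be told apart from the tumour type. A biological difference in these RNAs stays open and untested.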
